A study of Mus musculus with 2 samples.

How the data were processed

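The series holds 2 libraries of sorted mouse lung cells, 1 of E18.5 and 1 of postnatal day 10 (P10), which formed the 2 groups. Per the labels, lungs were digested with collagenase and dispase, red cells were sorted within the CD326-stained population, and libraries were made with a droplet-based kit that reads the 3' end of transcripts. Per the series design, tamoxifen was given to pregnant females by injection (0.1 mg per kg body weight) or in the diet (0.4 g per kg food) from embryonic day 12.5, and which route each library had is not given in the sources used here. The kit version in the labels and the barcodes in the files point to different kit generations, which was left open. The labels also give the P10 sample an embryonic tissue and both samples a reporter genotype other than that of the design text, and the group of each sample was taken from its time point.

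The deposited files hold raw UMI counts per gene and barcode, made by the authors with Cell Ranger 7.0.1, per the file headers, against mm10, per the submitters' processing notes. Those notes also name Seurat 4.0.0 without its role. Whether intronic reads were counted is not given in the sources used here, and the choice affects genes with long introns. The matrices list 32285 genes and no reporter or recombinase transcript. The deposited gene names and barcode lists carry no other measurement. Gene positions and lengths were taken from GENCODE vM21 on GRCm38, the assembly known as mm10, by Ensembl identifier. The length of a gene was counted from its first to its last base, introns included, and 8389 of 8392 measured genes had one.

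Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9. Cells were kept with at least 500 genes, at least 1000 UMIs and at most 20% mitochondrial UMIs, which left out 717 barcodes at E18.5 and 418 at P10, a few of them marked by Scrublet. Scrublet marked 5 cells at E18.5 (0.0416%) and 1 at P10 (0.00710%), so few that the caller has to be read as not having worked, and doublets therefore remain in the data. Scores were computed in double precision, after single precision had given scores that differed between runs, with the same cells marked. Each library was clustered on its own on counts scaled to 10000 per cell and log-transformed, with 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1, giving 24 clusters at E18.5 and 25 at P10.

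Clusters were named from markers of 16 classes that were fixed, like the gene lists, the intervals and a first set of alternative settings, before the data were examined. The rule that turns markers into names was set after the clusters were seen. A marker counted as raised when detected in at least 25% of a cluster's cells and at least 3 times above the 10th percentile over clusters, with 10 CPM added to both. A non-alveolar class needed at least 3 raised markers and at least 35% of its list. An alveolar class needed at least 3 raised markers and a median marker level of 0.5 on a scale from 0, that percentile, to 1, the highest cluster. A cluster was called mixed when the other alveolar class reached 0.25 on that scale, and transitional-like when its leading 10 genes held more transitional markers than markers of its alveolar class. Non-alveolar clusters carrying alveolar RNA above that level, 11.3% of E18.5 cells and 8.79% of P10 cells, were counted with their class in the shares and left out of summed profiles and of the background level. Under the alternative settings described below, the P10 share lay between 2.26 and 9.51%. The cells that form the background level would change with it. A cluster stayed unnamed where its leading 10 genes held more markers of another class, or where its depth was far below that of the library with no marker of its class among them. A cluster made up mostly of cells of 1 library cannot be parted from that library.

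Counts were summed over the cells of a class and expressed as CPM, counts scaled to the total of the sum. Ratios carry an exact conditional binomial interval, summed counts an exact Poisson interval and shares an exact binomial (Clopper-Pearson) interval, all at 95%, and a count of 0 was given the limit that 3 counts allow. Cells are not replicates, so no p-value, standard error or count of changed genes was made from them. Named genes were the 15 with the largest ratio in each direction among the 2797 genes with a mean of at least 50 CPM over both libraries, without mitochondrial, ribosomal, haemoglobin, sex-linked and unnamed gene models, together with members of the fixed lists, the markers and the genes of the sort. A list member counted as measured at 10 CPM or more in either sum and as higher or lower at a ratio of at least 2, and the median log2 ratio of a list was set among 10000 random lists of the same size matched on mean expression in 20 bins. A list was said to stand apart below the 2.5th or above the 97.5th percentile. Log2 ratios had 0.5 counts added to each sum. The background level of a gene was its median CPM over the non-epithelial classes of the same library, without erythroid-like and proliferating-like cells, and a gene was set against that of the library where it was higher, or within 1 library by its level in the higher class. At P10 the endothelial-like class in that median held only 17 cells. To compare detection across depths, cells were thinned to 3000 UMIs, and to 5000 UMIs for sex-linked genes.

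The ratio and list steps were tested on simulated counts of the AT2-like comparison over 32285 genes, of which 200 were changed. Median recovered ratios were 0.239 for genes changed to 0.25, 0.475 for 0.5, 1.91 for 2 and 3.81 for 4, and the intervals covered the true ratio for 94, 94, 98 and 90% of those genes and for 94.8% of unchanged ones. In the list step, over as many genes, a changed list reached percentile 100, and 7 of 200 unchanged lists fell outside the range, or 3.5%. The counts were drawn independently per gene and the unchanged lists at random, so these results check the computation only. How often a list of genes that vary together falls outside the range in these libraries was not tested.

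The first set of alternative settings held a stricter cell filter (1000 genes, 2000 UMIs, 10% mitochondrial), doublets kept, Leiden resolutions 0.5 and 2, joint clustering, other minimum levels of list members (1 and 50 CPM), totals without genes above 1% of counts, median-of-ratios scaling, the mean over cells of CPM, thinned detection and other numbers of markers. Chosen after the data were seen were leaving out the 8% of cells with the highest doublet scores, cells with only Xist or only Y-linked UMIs, AT2-like and transitional-like cells together, list members above the background level, and log2 ratios relative to the median of genes of the same length in 20 bins. The planned comparison of AT1-like cells between the time points was not made, since no P10 cluster was AT1-like, and the share of AT1 marker UMIs per cell was given in its place. Explanations of the acute-phase cluster at P10 had also been tested, and were set aside after their results were seen in favour of the tests on gene length. The values of those tests are given without weighing among the other observations.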

Results

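Single-cell RNA sequencing was carried out on lung cells of mice in which a tamoxifen-inducible recombinase under the control of Cdh16, the gene of kidney-specific cadherin, switched on the red fluorescent reporter tdTomato. Tamoxifen was given from embryonic day 12.5 onwards, so that red cells carry the mark of Cdh16 expression at or after that time. Cells that were red and stained for CD326, the surface protein encoded by Epcam, were sorted. There were 2 libraries, 1 from the fetal lung shortly before birth (E18.5) and 1 from postnatal day 10 (P10). Samples of embryonic day 16.5 were not analysed here. The E18.5 library held 12739 barcodes and 137837590 unique molecular identifiers (UMIs), and the P10 library 14503 barcodes and 171205348 UMIs. After filtering, 12022 cells with a median of 8956 UMIs and 2868.5 genes were kept at E18.5, and 14085 cells with a median of 10250 UMIs and 3149 genes at P10. With 1 library per time point, differences between time points have no replicate check. Both libraries carry the same batch label, and every interval given is a 95% interval that covers counting error only.

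The first question was whether the genes behind the labelling and the sort were still detected. Cdh16 (mm10, chromosome 8, 104601911 to 104624396, minus strand) was scarce, with 351 UMIs or 2.56 CPM (UMIs scaled to the library total, exact Poisson interval 2.30 to 2.84) at E18.5 and 131 UMIs or 0.767 CPM (0.641 to 0.910) at P10. At E18.5 its level was 2.86 CPM in AT1-like cells and 3.02 CPM in AT2-like cells, against 1.38 CPM (0.873 to 2.07) in non-epithelial cells. At P10 its level in AT2-like cells, 0.710 CPM, lay at or below the 0.781 CPM (0.337 to 1.54) of non-epithelial cells and was read as background. A Cdh16 UMI was seen in 2.59% of cells at E18.5 and 0.873% at P10, and after thinning every cell to 3000 UMIs in 0.720% and 0.166%. Epcam (chromosome 17, 87635979 to 87651129, plus strand), which encodes the adhesion protein used in the sort, stood at 329 CPM at E18.5 and 183 CPM at P10, and in non-epithelial cells at 162 and 55.8 CPM. An Epcam UMI was found in 80.6% of cells at E18.5 and 74.9% at P10, and after thinning in 58.7% and 39.5%, against 27.1% and 11.2% of thinned non-epithelial cells. These non-epithelial cells, taken without clusters that carried alveolar RNA, had median depths of 6711 and 4393 UMIs. Ptprc, the leukocyte gene CD45, was detected in 16.2% of cells at E18.5 and 19.7% at P10, or 7.76% and 9.43% after thinning. Pecam1, the endothelial gene CD31, was detected in 21.6% and 33.1%, or 7.95% and 14.95% after thinning. This was not confined to endothelial-like cells. In AT2-like cells it was detected in 20.3% and 29.6%, or 7.56% and 11.4% after thinning, against 18.8% and 31.7% of thinned non-epithelial cells. Before thinning, these non-epithelial cells included 327 endothelial-like cells at E18.5 but only 17 at P10. The larger endothelial-like cluster of P10, with 368 cells, carried alveolar RNA and was left out, so the 2 references are unlike. Thinning left out 1332 shallower cells at E18.5 and 823 at P10.

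The next question was which cell types the sorted cells were. The label of single cells could not be checked, as the matrices list no reporter transcript. At E18.5 the largest class was AT1-like, the thin gas-exchange cells of the alveolus, with 3746 of 12022 cells or 31.2% (exact binomial interval 30.3 to 32.0%). AT2-like cells, which make surfactant, were 22.0% (21.2 to 22.7%), and a further cluster of 2046 cells, 17.0% (16.4 to 17.7%), carried markers of both, though at Leiden resolution 2 no cluster was named so and 1505 cells stayed unnamed. Ciliated-like cells made up 3.73%, club-like cells 1.85% and neuroendocrine-like cells 0.175%. Non-epithelial classes made up 24.1% (23.4 to 24.9%) in spite of the sort on CD326, and the largest of them was myeloid-like at 13.9%. Of these 2899 cells, 1559 lay in clusters without alveolar RNA, as did 393 of the 1671 myeloid-like cells. In the other clusters a second cell in the droplet was not excluded. No cluster was transitional-like, although a stricter cell filter gave 1 such cluster of 548 cells, 4.89% (4.50 to 5.30%), with AT1 markers and led by Ccn2, Hbegf and Sfn among others. Of the 3 AT2-like clusters, 1 of 332 cells was led by the stress and antioxidant genes Sprr1a, Cbr3, Srxn1 and Gpx2, and 1 of 214 cells had a median of only 1599.5 UMIs. The cluster with both sets of markers was the deepest of the alveolar classes at E18.5, with a median of 16475.5 UMIs beside 5013.5 in AT1-like and 9126 in AT2-like cells.

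At P10 the AT2-like class held 9280 of 14085 cells or 65.9% (65.1 to 66.7%), and a transitional-like class, led by Areg, Sfn and Lgals3, held 1537 cells or 10.9% (10.4 to 11.4%), but 24.0% at resolution 2 and 25.1% when both libraries were clustered jointly. A second cell in some transitional-like droplets was not excluded. One of the 5 AT2-like clusters, of 956 cells, was led by the acute-phase genes Saa3, Orm1 and Lcn2, and another of 1283 cells held the stress gene Atf3 among its leading genes. No cluster was AT1-like by the naming rule, which concerns clusters and does not exclude single AT1 cells. The nearest was a cluster of 194 cells, 1.38% (1.19 to 1.58%), that was led by the AT1 genes Rtkn2, Akap5 and Hopx and also carried AT2 markers, and its share lay between 0.220 and 0.563% under resolutions 0.5 and 2, joint clustering or without the highest doublet scores. Its pooled levels of Hopx and Rtkn2 were 450 and 383 CPM, beside 16.2 and 4.62 CPM in AT2-like cells of the same library, but AT1 markers made up a median of only 0.417% of the UMIs of its cells and 27 of 194 cells reached the level usual in AT1-like cells of E18.5. Non-epithelial classes made up 19.4% (18.7 to 20.02%), among them myeloid-like at 6.62%, lymphoid-like at 6.30% and endothelial-like at 2.73%. Of these 2727 cells, 1489 lay in clusters without alveolar RNA. Clusters that stayed unnamed held 347 cells or 2.46%, of which 145 cells carried club and ciliated markers side by side and 202 had a median of 1609 UMIs. The shares depend on the sort and on clustering within each library, and since the genes that define a cluster differed between the libraries, they were not compared between time points.

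AT2-like cells were then compared between the time points, the question being how the sorted AT2-like cells differ after birth. The sums held 111262617 UMIs of 9280 cells at P10 and 27183160 UMIs of 2639 cells at E18.5. Dlk1 (ENSMUSG00000040856, chromosome 12, 109452823 to 109463336, plus strand), an imprinted Notch ligand of fetal tissues, showed the largest ratio, at 3336 CPM at E18.5 and 4.86 CPM at P10, 686 times higher at E18.5 (631 to 748). Also higher at E18.5 were Cldn10, a tight-junction claudin, by 62.3 times (57.6 to 67.4), and Mt2, a metallothionein, by 25.3 times (23.3 to 27.4). Retnla, a secreted resistin-like protein, was higher by 25.2 times (24.6 to 25.7), and Sprr1a, a cornified-envelope protein, by 23.1 times (21.0 to 25.5). Mirg, a noncoding RNA of the same imprinted domain as Dlk1, was higher by 22.2 times (20.3 to 24.3) and Qpct, glutaminyl cyclase, by 19.8 times (18.1 to 21.6). Higher at P10 were Saa3 (chromosome 7, 46711998 to 46715700, minus strand), an acute-phase serum amyloid, by 37.3 times (31.6 to 44.2), and Galnt13, a mucin-type glycosyltransferase, by 25.7 times (22.9 to 29.0). The antigen-presentation genes H2-Aa and H2-Ab1 were higher by 21.1 times (18.8 to 23.8) and 16.8 times (14.6 to 19.5), and Tmem132d by 17.4 times (16.6 to 18.3). Itih4, an inter-alpha-trypsin inhibitor chain, was higher by 14.6 times (13.0 to 16.4) and Acoxl, an acyl-CoA oxidase-like gene, by 11.6 times (11.1 to 12.1). Veph1 was higher by 10.9 times (9.68 to 12.4) and Klhl29 by 10.3 times (9.61 to 10.99). Saa3 was carried by the acute-phase cluster, at 1384 CPM. It stood at 36.0 CPM in the other AT2-like cells of P10 and at 5.26 CPM at E18.5. Both lay below its non-epithelial levels of 60.7 and 8.99 CPM, so a rise outside that cluster is not shown. Among AT2-like cells with Xist and no Y-linked UMI its log2 ratio was 3.41, and among those with Y-linked and no Xist UMIs 6.03. Sprr1a was carried by the antioxidant cluster, at 392 CPM there and 26.7 CPM in the other AT2-like cells of E18.5.

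Not all of the named genes stood clear of the RNA found in other cells. Of the 15 genes with the largest ratio towards P10, 6 were less than 2 times above their level in non-epithelial cells of that library, namely Thsd4, Ly6e, Fosb, Zbtb16, Fmo2 and Tacc1. The same held for 8 of the 15 genes with the largest ratio towards E18.5, Msln, Fstl1, Hopx, S100a14, Ass1, Tmem213, Cav1 and S100a6, and Hopx, at 742 CPM in AT2-like cells of E18.5, lay below its level in non-epithelial cells. Gene length moved with time point in every class that could be compared. In AT2-like cells the median log2 ratio of P10 over E18.5 was -0.66 for the shortest 20% of genes, up to 7.67 kb, and 0.94 for the longest 20%, from 111 kb. The same difference between the longest and the shortest genes, 1.60 in AT2-like cells, was 1.42 in fibroblast-like, 1.38 in pericyte or smooth muscle-like, 1.35 in myeloid-like and 0.69 in mesothelial-like cells. The named genes higher at P10 had a median length of 102 kb, with Galnt13 at 682 kb, Tmem132d at 651 kb and Thsd4 at 555 kb, and those higher at E18.5 a median of 11.3 kb. Set against genes of the same length, Galnt13 had a log2 ratio of 3.75, Tmem132d of 3.19, Acoxl of 2.60, Veph1 of 2.52 and Klhl29 of 2.43. By such ratios 10 of the 15 genes, Saa3, H2-Aa, Galnt13 and Tmem132d among them, stayed among the 15 largest, and Zbtb16, Acoxl, Veph1, Klhl29 and Tacc1 did not.

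**Figure D1:**
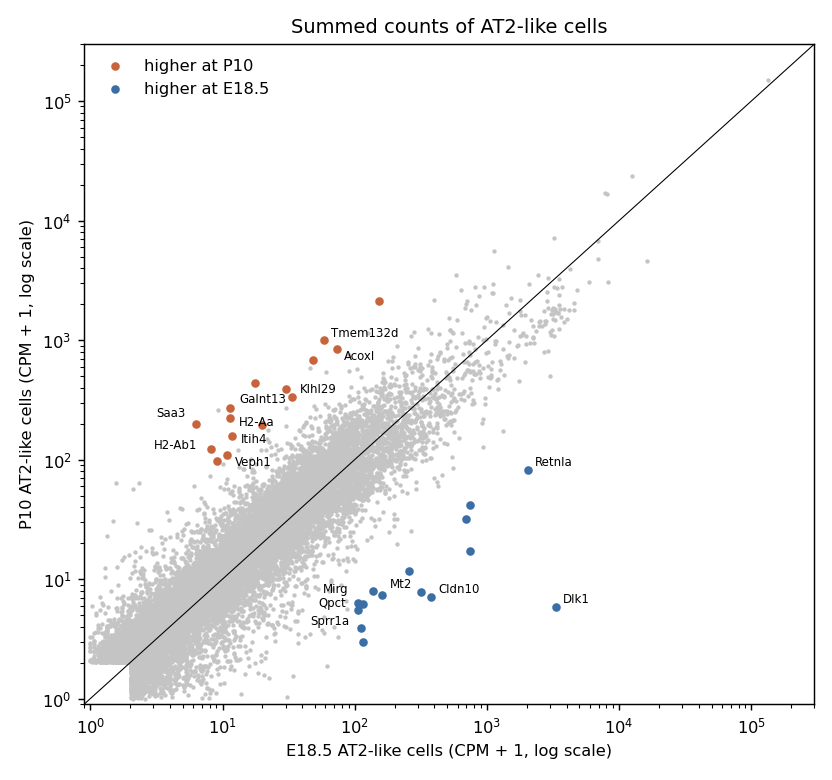
Level of each gene in the summed counts of AT2-like cells at E18.5 (x axis) and at P10 (y axis), as CPM plus 1 on log scales, with genes at 1 CPM or more in either library in grey and the 15 named genes of each direction in colour. Names are given for genes at least 2 times above their non-epithelial level, and Dlk1 lies farthest from the diagonal, at 3336 CPM against 4.86 CPM.

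Among 27 gene lists fixed beforehand, 3 stood apart from matched random lists towards P10. All 6 measured genes of MHC class II, which presents antigen to helper T cells, were at least 2 times higher, with a median log2 ratio of 3.26 (percentile 100), and Cd74, the invariant chain, stood at 125 CPM at E18.5 and 1147 CPM at P10. H2-Aa, H2-Ab1 and Cd74 exceeded their non-epithelial level by 2.10, 2.09 and 2.61 times, and in non-epithelial cells the list had a median of 3.53. Antimicrobial and airway defence had 8 of 11 measured members higher and 1 lower (median 1.43, percentile 99.96), among them Lcn2, an iron-sequestering lipocalin, with a log2 ratio of 2.58, C3, the central complement component, with 1.89, and Slpi, a protease inhibitor, with 1.91. Its lower member was Lyz1 (-1.44) and Lyz2 was higher (1.11), lysozyme genes so alike that counts may have been split between them. Lcn2 was partly carried by the acute-phase cluster, at 14047 CPM there. It stood at 2088 CPM in the other AT2-like cells of P10 and at 585 CPM in AT2-like cells of E18.5. Cholesterol synthesis had 8 of 17 members higher and none lower (median 0.83, percentile 99.6), such as Sqle (1.70) and Cyp51 (1.58), enzymes of the sterol pathway, but with members of at least 50 CPM alone its percentile was 79.9. Antimicrobial genes above the non-epithelial level had percentile 96.3, inside the random range. In non-epithelial cells these last lists had medians of 1.49 and 0.13.

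Towards E18.5, 7 lists stood apart. Imprinted and oncofetal growth genes had 7 of 10 measured members lower at P10 and none higher (median -2.34, percentile 0.00), with Dlk1 at -9.42, Hmga2, a fetal chromatin protein, at -3.22, Igf2, a fetal growth factor, at -2.67 and Meg3, an imprinted noncoding RNA, at -2.58. Hypoxia and glycolysis had 12 of 17 lower (median -1.65, percentile 0.00), such as Egln3, an oxygen sensor, at -4.16, Pgk1 at -2.30, Ldha at -1.74 and Gapdh at -1.73. The transitional cell state list had 11 of 12 lower (median -1.81, percentile 0.00), with Areg, an EGF receptor ligand, at -2.93 and Krt19, a keratin, at -2.87. The class rule partly sets this result, since 1537 transitional-like cells were left out of the P10 sum by these same markers and none at E18.5. In those cells Areg (619 CPM) and Krt19 (114 CPM) still lay below AT2-like cells of E18.5 (1317 and 427 CPM). Sfn lay above them (402 against 214 CPM). AT1 identity had 9 of 14 lower and 1 higher (median -2.57, percentile 0.00), but its 1 member more than 2 times above the non-epithelial level of the library where it was higher, the collagen gene Col4a3, went towards P10 at 1.26. Against the level of P10 alone others exceeded it too, such as Ager (668 against 209 CPM) and Lmo7 (519 against 181 CPM). BMP and TGF-beta targets had 4 of 9 lower (median -0.72, percentile 1.31), with Bambi at -2.51, and basement membrane and matrix 6 of 15 lower and 1 higher (median -0.59, percentile 0.370), with the laminin Lama3 at -2.48. The mitochondrial respiratory chain had 4 of 18 lower (median -0.73, percentile 0.30), such as Cycs, cytochrome c, at -1.41. In the library where a gene was higher, few members exceeded their non-epithelial level by 2 times, namely 3 of the imprinted genes, Dlk1 and Meg3 among them, 2 of the transitional list, among them Areg, 2 of basement membrane and none of hypoxia and glycolysis, BMP and TGF-beta targets or the respiratory chain. Thus Hmga2, Igf2, Egln3, Pgk1, Ldha, Gapdh, Krt19, Bambi, Lama3 and Cycs lay below that level at E18.5 or less than 2 times above it. At P10 other members of these lists exceeded it by 2 times, such as Krt8 (244 against 102 CPM) and Krt18 (398 against 156 CPM), and so did Bambi, Lama3 and Hmga2 (2.57 against 0.258 CPM). In non-epithelial cells of the same libraries the medians of these lists were -2.03 for imprinted genes, -1.58 for hypoxia and glycolysis, -2.12 for the transitional list, -2.61 for AT1 identity, -0.66 for BMP and TGF-beta targets, -1.13 for basement membrane and -0.63 for the respiratory chain. Set against genes of the same length, basement membrane moved to -1.35 and the respiratory chain to -0.38 (percentile 6.94), inside the range of random lists, where basement membrane also lay with members of 50 CPM (percentile 7.01).

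The remaining lists lay inside the range of random lists. Surfactant and lamellar body genes had 5 of 11 measured members higher (median 0.48, percentile 93.5), namely Sftpa1 (1.05), Sftpb (1.13), Sftpd (1.51), Abca3 (1.09) and Slc34a2 (1.15), while Sftpc (chromosome 14, 70520949 to 70524081, minus strand) stood at 0.17. Fatty acid and phospholipid synthesis had 4 of 16 higher and 1 lower (median 0.57), with Acaca, the rate-limiting carboxylase, at 1.58. The lung epithelial transcription factors had 3 of 17 higher and 3 lower (median -0.13), with Etv5 at 1.25, Nkx2-1, the lung lineage factor, at -0.12 and Sox9, a factor of the distal tip, at -3.11. Glycogen metabolism had 2 of 13 higher and 4 lower (median -0.29), among them Ppp1r3b at -4.17. Medians were 0.63 for MHC class I, 0.80 for interferon response, 0.44 for Wnt targets, 0.35 for FGF targets and 0.43 for Notch targets. They were -0.14 for YAP and TAZ targets (5 of 12 lower, none higher) and 0.12 for glucocorticoid-responsive genes (3 of 12 higher, 4 lower). For dissociation and immediate early genes the median was -0.01 (5 of 16 higher, 3 lower). The others were 0.35 for ion and water transport, 0.03 for antioxidant defence, -0.44 for epithelial junctions and cadherins and -0.12 for G1/S and DNA replication. Only 1 gene of G2/M and mitosis was measured, too few for a median. The median log2 ratio over all genes of at least 10 CPM was 0.20, and scaling by the median of ratios moved every log2 ratio by -0.16. The AT2-like class consisted of 3 clusters at E18.5 and 5 at P10, and percentiles describe these libraries only. Relative to genes of the same length, the lists of surfactant (0.61, percentile 99.1), fatty acid synthesis (0.34, percentile 98.7), MHC class I (0.80, percentile 99.3), interferon response (1.16, percentile 99.9), immediate early genes (0.35, percentile 98.6), YAP and TAZ targets (-0.73, percentile 0.100) and glycogen metabolism (-0.46, percentile 2.10) came to lie outside the range of random lists. Over all alternative settings, 15 of 179 values of these 16 remaining lists lay outside it.

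**Figure D2:**
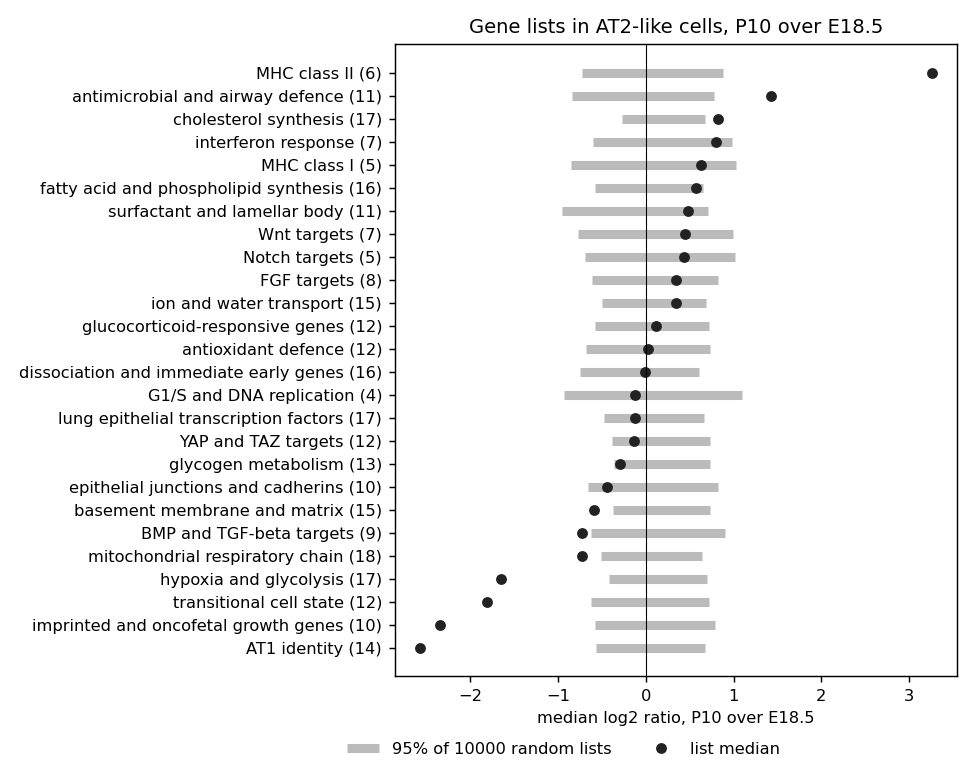
Median log2 ratio of P10 over E18.5 in AT2-like cells for each gene list, with the number of measured members in brackets, as points, and the range of 95% of 10000 random lists matched on mean expression as grey bars. MHC class II lies farthest to the right at 3.26 and AT1 identity farthest to the left at -2.57.

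Within the E18.5 library, AT1-like and AT2-like cells were compared over the same lists without the markers used to name the classes. Other genes that may have shaped the clusters were kept. Among these were Ccn2, a leading gene of an AT1-like cluster, and Lyz1, a leading gene of an AT2-like cluster. The medians and percentiles may thus partly follow from the clustering. Basement membrane and matrix genes had 13 of 14 measured members at least 2 times higher in AT1-like cells and 1 lower (median 1.81, percentile 100), with Col4a4 at 3.03, Fras1 at 2.71, the proteoglycan Agrn at 2.51 and Npnt, nephronectin, at 2.13. YAP and TAZ targets, which respond to cell stretch, had 8 of 13 higher and 1 lower (median 1.42, percentile 99.99), such as Ccn2 (2.52) and Ajuba (2.42). Epithelial junctions and cadherins had 5 of 9 higher (median 1.16, percentile 99.5), with Tjp1 at 2.00, and interferon response 4 of 8 (median 1.02, percentile 99.7), with Ifit3 at 3.02, of which 1 member exceeded its non-epithelial level by 2 times. In AT2-like cells all 6 antimicrobial genes were higher (median -3.09, percentile 0.00), Lcn2 by -3.79 on the scale of AT1-like over AT2-like cells. So were 3 of 6 Wnt targets (median -1.15, percentile 0.770), with Lgr5 at -2.52, and 4 of 12 antioxidant genes against 1 the other way (median -0.84, percentile 0.00). The same held for 7 of 15 genes of fatty acid and phospholipid synthesis against 2 (median -0.69, percentile 0.0100), with Scd1 at -3.70 and Fasn, fatty acid synthase, at -2.08. Smaller medians outside the random range were those of cholesterol synthesis (-0.45), lung epithelial transcription factors (-0.27), ion and water transport (-0.15) and hypoxia and glycolysis (-0.09). Ion and water transport held the sodium channel genes Scnn1b (3.06) and Scnn1g (3.32) beside the chloride channel gene Cftr (-2.99), and over members above the non-epithelial level its median was 0.71. With only members above the non-epithelial level, the lists of YAP and TAZ targets (median 1.54), junctions (1.16), Wnt targets (-1.46), ion transport, antioxidant defence (-1.65) and transcription factors (-0.84) lay inside the random range, as did junctions with members of 1 CPM (0.59) and hypoxia with members of 50 CPM. The same comparison could not be made at P10, where no cluster was AT1-like.

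**Figure D3:**
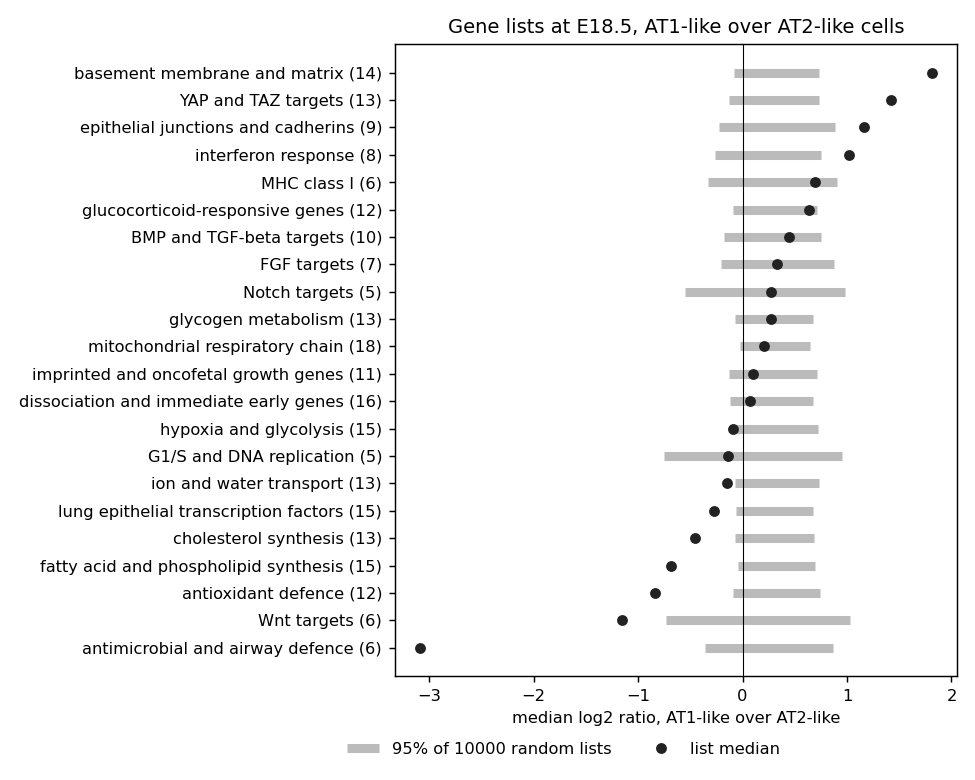
Median log2 ratio of AT1-like over AT2-like cells at E18.5 for each gene list without class markers, with the number of measured members in brackets, as points, and the range of 95% of 10000 matched random lists as grey bars. Basement membrane and matrix lies farthest to the right at 1.81 and antimicrobial and airway defence farthest to the left at -3.09.

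Whether single sorted cells carried both alveolar programmes was the last question. After thinning to 3000 UMIs, at least 3 AT1 markers and at least 3 AT2 markers were detected together in 96.3% of cells at E18.5 (95.9 to 96.7%) and in 71.0% at P10 (70.2 to 71.8%). Non-epithelial cells, which should lack both, reached 89.9% at E18.5 and 22.7% at P10, at median depths of 6711 and 4393 UMIs before thinning, against 8956 and 10250 UMIs over all cells. The E18.5 share therefore measures mostly background RNA of both programmes, and the P10 share contains it. AT1 markers made up a median of 2.66% of the UMIs of an AT1-like cell at E18.5 and 0.195% of those of an AT2-like cell at P10. A share of 1.71%, which 95% of AT1-like cells of E18.5 exceeded, was reached by 34.5% of all E18.5 cells (33.6 to 35.3%) and by 30 of 14085 P10 cells, or 0.213% (0.144 to 0.304%), of which 27 lay in the cluster of 194 cells led by AT1 genes.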

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

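The tests on random pairs, on free RNA in the E18.5 cluster with both marker sets, on hidden AT1-like cells and on gene length alone were chosen only after the result was seen. Xist, the noncoding RNA of the inactive X chromosome, and Y-linked genes belonged to no comparison and were looked at as a signal that the comparisons had left unused. The E18.5 library held 15433 UMIs of Xist and 12406 UMIs of Y-linked genes, and the P10 library 39228 and 14116, so that both held cells of females and males. Cells with Xist and no Y-linked UMI made up 35.2% at E18.5 (34.4 to 36.1%) and 48.7% at P10 (47.8 to 49.5%), and cells with Y-linked and no Xist UMIs 25.5% (24.8 to 26.3%) and 17.6% (17.0 to 18.3%).

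The cluster of 2046 E18.5 cells with AT1 and AT2 markers had 3 technical explanations. Random pairs of an AT1-like and an AT2-like cell would bring Xist and Y-linked UMIs together, but these shared a cell at 0.418 of the chance level, below all 100 simulated sets of pairs (0.591 to 0.804). Free RNA of AT1-like cells stays open. The median AT1 marker stood at 0.731 of the highest non-epithelial cluster with none of 15 above it, but some clusters hold alveolar RNA that may come from a second cell. It stood at 1.29 times the highest class without such clusters with 11 of 15 above it, where the choice of classes sets the outcome. In a myeloid-like cluster with AT2 RNA (median 26850 UMIs), Xist and Y-linked UMIs shared a cell at 0.794 of the chance level. That lay inside the range of simulated pairs with AT2-like cells (0.477 to 1.05), against 0.4185 and 0.421 in AT1-like and AT2-like cells. Cells of the same animal that stayed attached fitted, with a median absolute log2 deviation of 0.0901 from the summed profile of both classes over 308 genes and none of 3014 genes 1.5 times or more above both. Free RNA added to AT2-like cells, or a cell type that carries both programmes at this stage, would look alike in this test, so the biological explanation stays open as untested.

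The small number of AT1-like cells at P10 was set against 2 technical explanations. The filter removed few cells with the AT1 marker share of E18.5 AT1-like cells, since 0.957% of the barcodes left out (4 of 418, 0.261 to 2.43%) reached it. Few cells of that share were hidden in other clusters, since 0.213% of all kept P10 cells reached it (0.144 to 0.304%). Neither test can see P10 AT1 cells with a lower share, as only 27 of 194 cells in the cluster led by AT1 genes reached it. In the P10 cluster of 194 cells led by AT1 genes, Xist and Y-linked UMIs shared a cell at 0.575 of the chance level, inside the range of simulated random pairs of AT2-like cells (0.525 to 1.04) and near the 0.519 of AT2-like cells, which does not decide. Such pairs could not give a cluster led by AT1 genes in any case, with Rtkn2 at 383 CPM there against 4.62 CPM in AT2-like cells. Leaving them out was thus settled before the test and says nothing on what the cluster is. The cluster was also shallower, with a median of 9712 UMIs against 21565 in the simulated pairs. Pairs of an AT1 with an AT2 cell were not tested there. Loss of AT1 cells in digestion or sorting, and a difference of age in what labelled cells become, were not tested.

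Long genes were frequent among those higher at P10 in AT2-like cells, with 7 of 15 in the longest 20% of genes against 0 of 15 among those higher at E18.5. More unspliced RNA counted throughout the P10 library fitted, since the longest genes exceeded the shortest by a median log2 of 1.37 over 4 non-epithelial classes (0.69 to 1.42), although gene counts do not show unspliced reads themselves and other causes shared by all cells were not parted from it. Gene length alone stays open as the cause, since after setting each ratio against genes of the same length 20% of the 15 largest ratios (3 genes, 4.33 to 48.1%) belonged to the longest 20% of genes, an interval that still holds the 46.7% found before. Among the 100 largest ratios the share fell from 56% to 26% (17.7 to 35.7%), beyond its interval, but centring by length brings either share towards 20% by construction, so that the fall decides nothing. A biological difference of age shared by all classes was not tested.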

How the results depend on the processing

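Leaving out the highest doublet scores, using cells with only Xist or only Y-linked UMIs, joining AT2-like with transitional-like cells, keeping members above the non-epithelial level and setting genes against others of the same length were chosen only after the result was seen. No paired analysis was possible because each time point had 1 library. The alternatives for AT1-like cells between time points were not run, as P10 had no AT1-like cluster. Of 270 values of named genes none reversed, with 149 inside and 121 outside the counting interval. The named genes were chosen for the largest ratios, which left little room for a reversal, so its absence says little. Of 112 values of the 10 lists that stood apart in AT2-like cells, 106 medians were counted as the same, 6 as moved and none as reversed. Counted apart from that, 5 values came inside the random range, some of them with a median counted as the same. Depth limits the detection of scarce genes such as Cdh16.

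The stricter filter gave 24.6% AT1-like, 18.9% AT2-like, 22.0% mixed and 4.89% transitional-like cells at E18.5, where no other setting gave a transitional-like cluster, and 64.3% AT2-like, 14.5% transitional-like and 17.97% non-epithelial cells at P10. With doublets kept, AT2-like and mixed cells of E18.5 were 23.2% and 15.8%, and transitional-like and mixed cells of P10 10.2% and 1.73%. Resolution 0.5 gave 20.3% and 18.7% for AT2-like and mixed cells of E18.5, and 67.0% and 0.504% at P10. Resolution 2 gave 27.1% and 0% at E18.5, but left 1505 cells (12.5%) with a median of 16600 UMIs unnamed, and 53.8% AT2-like, 24.0% transitional-like and 0.412% mixed cells at P10. Joint clustering gave 19.8% and 19.5% for AT2-like and mixed cells at E18.5, and 53.4% AT2-like, 25.1% transitional-like and 0.220% mixed cells at P10. Without the highest doublet scores, AT1-like and non-epithelial cells of E18.5 were 33.2% and 21.5%, and AT2-like, mixed and non-epithelial cells of P10 68.0%, 0.563% and 18.05%. This last setting was fragile, since scoring doublets in single precision changed by rounding between runs and in 1 run moved AT2-like and mixed cells of E18.5 beyond their counting intervals.

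Thinning lowered detection by construction, at E18.5 to 0.720% for Cdh16, 58.7% for Epcam, 7.76% for Ptprc and 7.95% for Pecam1, and at P10 to 0.166%, 39.5%, 9.43% and 14.95%. Cells with both programmes were 99.3% and 88.9% with 2 markers of each, and 87.95% and 45.1% with 4, at E18.5 and P10.

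In AT2-like cells, members of 50 CPM gave -1.81 for AT1 identity, 3.69 for MHC class II and -1.17 for BMP and TGF-beta targets, cells with only Y-linked UMIs -2.26 for the transitional list, and genes of the same length -1.35 for basement membrane and -0.38 for the respiratory chain (percentile 6.94). Inside the random range came also cholesterol synthesis with members of 50 CPM (percentile 79.9) or above the non-epithelial level (89.7), antimicrobial genes above that level (96.3) and basement membrane with members of 50 CPM (7.01).

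Between AT1-like and AT2-like cells of E18.5, median-of-ratios scaling gave -0.99 for fatty acid synthesis, -0.76 for cholesterol synthesis, 0.72 for interferon response, 1.51 for basement membrane, 1.12 for YAP and TAZ targets, -0.40 for hypoxia, -0.46 for ion transport, -1.15 for antioxidant defence, -0.58 for transcription factors and 0.86 for junctions. Members of 50 CPM gave -1.02 for fatty acid synthesis, -0.69 for cholesterol synthesis and -3.71 for antimicrobial genes, and members of 1 CPM 1.33 for interferon response, -0.69 for Wnt targets and 0.59 for junctions. Members above the non-epithelial level gave -2.08 for fatty acid synthesis, -3.71 for antimicrobial genes, 2.13 for basement membrane, -1.65 for antioxidant defence and -0.84 for transcription factors, and reversed ion transport to 0.71. Of 55 values of these 12 lists, 8 came inside the random range, namely with members above the non-epithelial level YAP and TAZ targets (median 1.54, percentile 85.0), Wnt targets (-1.46, 26.6), ion transport (40.9), antioxidant defence (8.39), transcription factors (13.1) and junctions (1.16, 55.4), with members of 50 CPM hypoxia (3.07), and with members of 1 CPM junctions (93.5). Other than for ion transport and junctions of 1 CPM these medians kept their direction and about their size or grew, while the random lists then also held only genes above that level. The cause was not tested.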

Other observations

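The comparison of transitional-like with AT2-like cells at P10, and the genes of the 2 clusters described here, were chosen only after the result was seen. At P10 the immediate early genes, which respond to stress and to dissociation, had a median log2 ratio of 0.59 of transitional-like over AT2-like cells (percentile 100), with 1 of 15 measured members, Ier3 (1.16), at least 2 times higher, and only Atf3 (0.94) at least 2 times above the non-epithelial level. YAP and TAZ targets had 3 of 10 members at least 2 times higher (median 0.41, percentile 99.98), namely Ptpn14 (1.81), the coagulation factor receptor F3 (1.54) and Ccn1 (1.02). Ptpn14 was itself among the leading genes of the transitional-like cluster, so these list results may partly follow from the clustering. BMP and TGF-beta targets had 1 of 9 members higher, Id3 (1.05), and a median of 0.46 (percentile 99.96), but Id3, at 148 CPM, lay below its non-epithelial level of 329 CPM, as did Ier3 at 228 against 306 CPM. Notch targets (median 0.38, percentile 99.6), MHC class II (0.25, 98.4) and epithelial junctions (0.22, 98.6) also lay above the random range, with no member at least 2 times higher. Cholesterol synthesis (median -0.45, percentile 0.00) and fatty acid synthesis (median -0.35, percentile 0.00) lay below the random range, with 0 of 17 and 0 of 16 members at least 2 times lower and Scd1, a desaturase, at -0.74. So did antimicrobial genes (median -0.32, percentile 0.120), though Cxcl1 was higher (1.49). Xist and Y-linked UMIs shared a cell at 0.659 of the chance level in transitional-like cells and at 0.519 in AT2-like cells of P10. A second cell in some transitional-like droplets was thus not excluded. By the naming rule the class was found at E18.5 only under the stricter filter (4.89%), in a cluster with AT1 markers, and its genes include those of dissociation stress. That rule looks at leading genes within a library, so it does not show that the markers were lower at E18.5. In AT2-like cells of E18.5 Areg stood at 1317 CPM and Krt8 at 530 CPM, above the 619 and 472 CPM of transitional-like cells at P10. Sfn went the other way (214 against 402 CPM), and Krt8 was near its non-epithelial level at E18.5 (410 CPM).

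At E18.5 a cluster of 332 AT2-like cells was led by genes of antioxidant defence. Relative to the other AT2-like cells of E18.5, the peroxidase Gpx2 was 23.2 times higher (17.2 to 32.0), Cbr3, a carbonyl reductase, 22.6 times (20.1 to 25.5), Srxn1, sulfiredoxin, 17.96 times (14.98 to 21.7), Nqo1, a quinone reductase, 8.82 times (6.71 to 11.7) and Gclm, of glutathione synthesis, 5.37 times (4.92 to 5.86). Sftpc stood at 0.642 and Dlk1 at 0.511 of the level in the other cells.

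At P10 a cluster of 956 AT2-like cells, 10.3% of the class, was led by acute-phase genes, with Saa3 at 38.4 times, Orm1 at 28.1 times, Lcn2 at 6.73 times and Lrg1 at 5.28 times the level of other AT2-like cells. Their summed level was 16686 CPM, against 2247 CPM in the highest non-epithelial class. Cells with only Y-linked UMIs made up 46.9% of this cluster (43.7 to 50.1%) and 14.6% of the other AT2-like cells, and 27.0% of the 1662 AT2-like cells with only Y-linked UMIs lay in it. Outside the cluster Saa3 stood at 34.1 CPM in cells with only Y-linked UMIs and at 35.4 CPM in cells with only Xist. Inside it the levels were 1438 and 708 CPM. RNA of another cell type, sex and a single animal of a mixed pool had been tested as explanations of this cluster, and these tests were set aside after their results were seen, so that the values stand here without an explanation.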
